A study of Mus musculus with 25 samples.

How the data were processed

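Small RNA of the mouse hypothalamus was sequenced in 25 libraries of 8 groups, 13 from males and 12 from females, with QIAseq miRNA libraries that carry unique molecular identifiers (UMIs). The files list fold changes and p-values per miRNA and comparison, and no value per sample was used here. The fold is the ratio of the test group to the control group after normalisation with DESeq2 by the authors, per the file headers, and is given to 2 decimals. The p-value is the unadjusted value that DESeq2 returned to the authors, per the file headers, and its version is not given in the sources used here. Fold regulation, per the file headers, is the fold or minus its inverse where the fold is below 1. A remark deposited by the authors marks miRNAs whose mean UMI count was below 10 in a group, in both groups, or 0 in both. The aligner, counting rule and annotation are not given in the sources used here, and build mm10 is named in the submitters' processing notes. Near-identical miRNAs, such as the let-7 family, can share reads, so values of single members are uncertain. The depth per library is unknown, so precision was judged from the spread behind each deposited p.

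The males are in 1 table, with HCD-HCD, HCD-RD and RD-HCD each compared with RD-RD. The HCD-RD females were normalised in a separate table from the other females, with the same RD-RD libraries. A further deposited list compares HCD-HCD with RD-HCD males and holds miRNAs at a fold of at least 2 and p up to 0.05. The 3 RD-HCD male libraries carry other numbers in the workbook than in the sample titles, under the same group code, so single libraries of that group could not be matched. The sample sheets list 43 libraries, of which 18 were not analysed here. Order numbers in library names can be split into 3 complete sets in 2 ways, and only 1 RD-HCD male library changes set between them.

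Each table has 1721 entries, of which 1618 are miRNAs and 103 are piRNAs, left out of the tests. P-values were adjusted by Benjamini-Hochberg over the miRNAs with a p in a comparison, and called at an adjusted p under 0.05. A standard error of the log2 fold was taken as its size over the normal score of the deposited p, and not given for a log2 fold under 0.1 in size. Intervals of 95% use that error. Lists were tested with limma's cameraPR on signed normal scores of the p-values at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 96 tests of 16 lists in 6 comparisons. The lists were neuron-enriched, hypothalamus and neuroendocrine, inflammation-related, microglia and blood leukocyte, erythrocyte, endothelial and mural, oligodendrocyte, choroid plexus and ependymal, muscle and liver, let-7 and miR-98, miR-30, miR-29, miR-17 to miR-92, lipid and glucose metabolism, the Dlk1-Dio3 cluster and the Sfmbt2 cluster. Some miRNAs are in more than 1 list, such as miR-155-5p among both inflammation-related miRNAs and leukocyte markers.

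Lists and the rule for named miRNAs were fixed before the data were examined. Named were per comparison the 10 smallest p-values among higher and the 10 among lower miRNAs with an unadjusted p under 0.05, every list member at an adjusted p under 0.05, and up to 4 members per list with the smallest p. Contrasts between male groups combined deposited log2 folds over miRNAs with no remark in the 3 male comparisons. Their errors came from the implied spread and the number of libraries in each group, with the shared RD-RD libraries counted once, and a normal test was used. The library set test set the log2 fold of RD-HCD males against the log2 of the mixed mean that a set would give, with 0 or 1 of the 3 libraries outside it. Those contrasts, the difference test between sexes, the library set test, the correlations of miRNA pairs, the alternatives without low-count miRNAs for lists, overlaps and sexes, and adjustment with piRNAs included were chosen after the data were seen. Unchanged groups against shared controls were simulated with 100 draws, and pairs were shuffled 1000 times, with neighbouring hairpins taken within 10000 bp. Hairpin positions came from GENCODE M21 on GRCm38, and 48 of 1618 names had no match. Each matched name was placed at 1 hairpin copy only.

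Other settings, fixed together with the lists, were a fold of at least 1.5 or 2, an unadjusted p under 0.01, only miRNAs with no remark, Benjamini-Yekutieli and Holm adjustment, centred folds, a preset correlation of 0.05, log2 fold or ranks in the list test, Pearson correlation, and, between the sexes, only miRNAs at an unadjusted p under 0.05 in one sex. A test on counts, the first choice then, was not used because the tables hold folds and p-values. Calls were tested on simulated data with 200 changed miRNAs among those with no remark. At 1.5-, 2- and 3-fold, 11.5%, 67% and 97% were recovered for HCD-HCD males, 19.5%, 71% and 94% for HCD-RD males, and 11.5%, 68.5% and 94% for RD-HCD males. In females, 1.5%, 51.5% and 94% were recovered for HCD-HCD, 10%, 64% and 97% for HCD-RD, and 0.5%, 47% and 92% for RD-HCD. False calls made up at most 7.84% of calls, in RD-HCD females at 2-fold. At 3-fold the difference tests recovered 97% for HCD-HCD minus RD-HCD males (743 miRNAs) and 79.5% for HCD-RD males minus females (695 miRNAs), and the library set test recovered 99.5% (715 miRNAs, 1 library outside the set). In simulated HCD-HCD males, let-7 shifted by 1 in the score was recovered in 57% of 100 draws and by 2 in 100%. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.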

Results

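MicroRNAs (miRNAs), small RNAs that lower the translation and stability of their target messenger RNAs, were measured in the hypothalamus of C57BL/6J mice aged 3 months. Dams were fed a regular diet (RD) or a hypercaloric diet (HCD, 52% fat with high sucrose) from 1 month before mating through pregnancy and lactation, and their offspring then ate RD or HCD. Groups are named by the dam's diet and then the offspring's diet, so HCD-RD marks offspring on RD born to dams on HCD. In males there were 4 RD-RD libraries and 3 each of HCD-HCD, HCD-RD and RD-HCD, and in females there were 3 libraries in each of the same 4 groups. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples, which may be technical. They give no dam or litter either, so libraries of the same maternal diet may share dams. The comparisons ask how the diet of the dam, of the offspring and of both changed hypothalamic miRNAs in each sex. Folds and p-values come from the authors' deposited tables, which give 1 fold and 1 p per miRNA and comparison, and the depth of the libraries is unknown. The order numbers in the library names fall into 3 sets, with the RD-RD libraries of both sexes and the RD-HCD females in one set. All HCD-HCD and HCD-RD libraries and at least 2 of the 3 RD-HCD male libraries lie in another set, so set and group run together in comparisons with RD-RD, except in RD-HCD females and, for 1 library, possibly in RD-HCD males.

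Males on HCD born to dams on HCD had lower levels of miR-33-5p, which represses the cholesterol exporter Abca1, and of miR-142a-5p, a miRNA of blood and immune cells. In the authors' deposited table, miR-33-5p fell to 0.25 of the RD-RD level (log2 fold -2.0, standard error 0.31 implied by the deposited fold and p), with adjusted p = 8.4e-08. The same table, the authors' deposited table for males, put miR-142a-5p at 0.256 of the RD-RD level (log2 fold -1.97, implied standard error 0.32, adjusted p = 8.6e-07). Members of the let-7 family, which mark differentiated cells and oppose Lin28, rose together, led by let-7b-5p at 2.22-fold in the authors' deposited table (log2 fold 1.15, implied standard error 0.24, adjusted p = 7.7e-05). The related miR-99a-5p and miR-100-5p, which share a seed, each rose to 2.43-fold in the authors' deposited table, with implied standard errors of 0.22 and 0.24 on the log2 scale and adjusted p-values of 9.8e-07 and 1.6e-05.

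The hairpin of miR-33-5p lies in an intron of Srebf2, the gene of a transcription factor of cholesterol synthesis, on chromosome 15 from 82198122 to 82198190. The hairpin of miR-142a-5p lies in an intron of Mir142hg on chromosome 11 from 87756864 to 87756927. That of let-7b-5p overlaps an exon of the long noncoding gene Lncppara on chromosome 15 from 85707319 to 85707403. The hairpin of miR-99a-5p is intronic in Mir99ahg on chromosome 16 from 77598936 to 77599000, and a let-7c-5p hairpin follows in the same host gene from 77599657 to 77599750. Positions are from GENCODE M21 on GRCm38, the mm10 build.

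Other miRNAs also fell in HCD-HCD males. From the miR-101 group, miR-101a-5p and miR-101c stood at 0.252 and 0.189 of the RD-RD level, in the authors' deposited table, with adjusted p-values of 1.2e-05 and 1.6e-05. Also lower in the authors' deposited table were miR-301a-3p at 0.321 (intron of Ska2) and miR-296-5p at 0.27. Among those that rose, miR-350-3p reached 2.95-fold, miR-374b-5p 2.86-fold and miR-365-3p 2.51-fold in the authors' deposited table. Both arms of the miR-15b hairpin, a relative of miR-16 in an intron of the condensin gene Smc4, rose to 1.95-fold (5p) and 2.75-fold (3p) in the authors' deposited table. In all, 275 of 1426 miRNAs with a p passed an adjusted p under 0.05, 80 higher and 195 lower, against 463 at an unadjusted p under 0.05 where 71.3 were expected by chance. Of the 275, 106 carried the authors' remark of a mean below 10 molecules in a group. Adjusted over the 757 miRNAs with no such remark, 177 passed, 87 higher and 90 lower, so the share of higher calls was 29.1% over all and 49.2% without remarks. The median log2 fold of all miRNAs was -0.26 in HCD-HCD, -0.25 in HCD-RD and -0.12 in RD-HCD males, and 0.06 in HCD-HCD males over miRNAs with no remark.

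**Figure D1:**
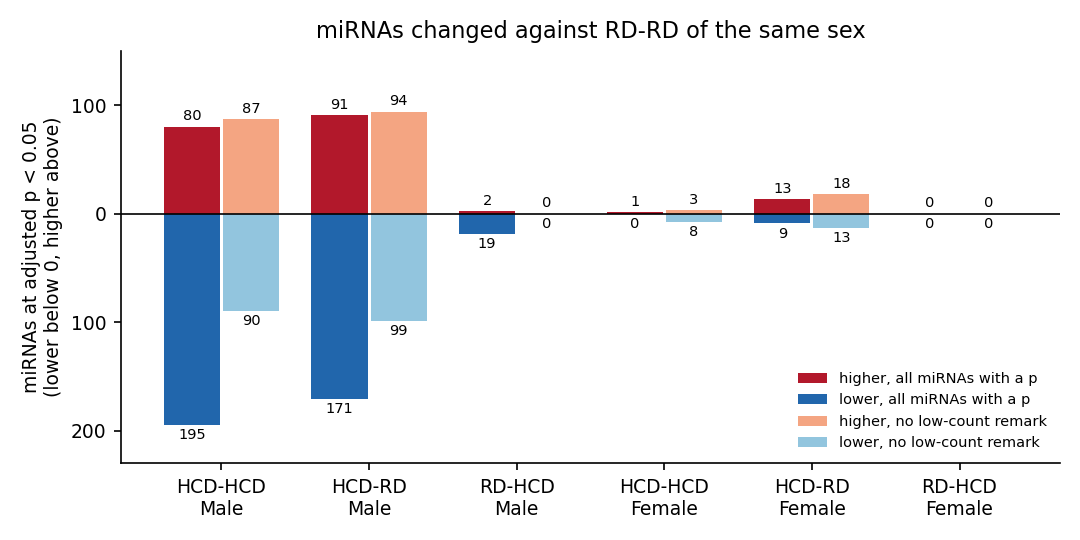
miRNAs higher (above 0) and lower (below 0) against RD-RD of the same sex at an adjusted p under 0.05, for the 6 comparisons. Dark bars count all miRNAs with a p and pale bars only those with no low-count remark; HCD-HCD and HCD-RD males have 275 and 262 in all, and RD-HCD females have 0.

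The let-7 and miR-98 family was the list with the clearest common direction in HCD-HCD males. Of its 11 members 9 rose, 10 when adjusted over the list alone, and none fell, with a median fold of 1.67 and a list test by limma's cameraPR at adjusted p = 1.8e-10. Further members were let-7f-5p at 2.13-fold, let-7g-5p at 2.04-fold and miR-98-5p at 2.47-fold of RD-RD in the authors' deposited table. The members differ by few bases, and reads shared between them could not be separated here.

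Of the 18 inflammation-related miRNAs, 4 rose and 2 fell (5 and 2 adjusted over the list alone), with cameraPR adjusted p = 0.0012. The list call ended without the low-count miRNAs (adjusted p = 0.12, a restriction chosen after the data were seen), and stood at adjusted p = 0.03 with a preset correlation of 0.05. Those that rose were miR-155-5p, an inducer of the inflammatory response, miR-125b-5p, miR-125a-5p and miR-99b-5p, at 2.47-, 1.7-, 1.6- and 1.7-fold in the authors' deposited table. The pair that fell was miR-21a-3p at 0.37 and miR-181c-5p at 0.457 of RD-RD in the authors' deposited table. Because no values per sample were used, a correlation between miRNAs could not be estimated, and the preset value of 0.05 stands in its place.

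The imprinted Dlk1-Dio3 cluster on chromosome 12, whose miRNAs are expressed from the maternal allele, moved in both directions. Of 100 measured members 10 rose and 24 fell (12 and 27 adjusted over the list alone), and cameraPR found no common direction (adjusted p = 0.6), with a median log2 fold of 0.04 and a mean of -0.14. Members that fell included miR-376a-3p at 0.389, miR-341-3p at 0.442, miR-136-5p at 0.431 and miR-377-3p at 0.282 of RD-RD in the authors' deposited table. Among those that rose, miR-329-3p stood at 2.3-fold and miR-487b-3p at 2.03-fold in the authors' deposited table. In the Sfmbt2 intron cluster on chromosome 2, 3 of 38 members rose and 4 fell, the same adjusted over the list alone, with cameraPR adjusted p = 0.09. The lowest was miR-297b-5p, with a low-count remark, at 0.182 of RD-RD in the authors' deposited table.

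Of the 16 lipid and glucose miRNAs 3 fell and 0 rose (the same adjusted over the list alone), namely miR-33-5p, miR-144-3p and miR-758-3p, with cameraPR adjusted p = 0.51. In the miR-17 to miR-92 clusters, which promote cell growth, 2 of 12 rose and 4 fell (3 and 5 adjusted over the list alone), with cameraPR adjusted p = 0.97. miR-25-3p stood at 1.79-fold and miR-19a-3p at 0.366 of RD-RD in the authors' deposited table. In the miR-29 family 1 of 6 rose and 1 fell (the same adjusted over the list alone; cameraPR adjusted p = 0.86), and in the miR-30 family 0 of 7 rose and 2 fell (1 and 2 adjusted over the list alone; cameraPR adjusted p = 0.74, upward, against a mean log2 fold of -0.06). Of 15 hypothalamic and neuroendocrine miRNAs, 1 rose (miR-7a-1-3p) and 1 fell (miR-96-5p), the same adjusted over the list alone. That list's cameraPR adjusted p was 0.74, with the test upward against a median log2 fold of -0.20, since it compares the list's scores with those of all other miRNAs.

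Single members of the cell type marker lists also passed in HCD-HCD males, while no marker list did. Of 18 neuron-enriched miRNAs 1 rose and 2 fell (the same adjusted over the list alone; cameraPR adjusted p = 0.18), with miR-129-2-3p at 1.42-fold and miR-153-3p at 0.448 of RD-RD in the authors' deposited table. Of 8 microglial and leukocyte markers 1 rose and 2 fell (1 and 3 adjusted over the list alone; cameraPR adjusted p = 0.92): miR-155-5p was higher while both arms of miR-142a were lower. Of 9 choroid plexus and ependymal markers 3 rose and 2 fell (the same adjusted over the list alone; cameraPR adjusted p = 0.52), with miR-204-5p at 2-fold and miR-34b-5p at 0.364 of RD-RD in the authors' deposited table. Of 10 endothelial and mural markers 2 rose and 0 fell (2 and 2 adjusted over the list alone; cameraPR adjusted p = 0.25), led by miR-145a-3p at 2.54-fold in the authors' deposited table. Among 5 oligodendrocyte markers miR-338-5p rose and miR-219a-5p fell (the same adjusted over the list alone; cameraPR adjusted p = 0.56). Among 6 erythrocyte markers 0 rose and 1 fell, miR-144-3p (the same adjusted over the list alone; cameraPR adjusted p = 0.62), with a median log2 fold of 0.30 and a mean of -0.10. None of 8 muscle and liver markers passed in either setting, over all miRNAs or adjusted over the list alone, with 1 at an unadjusted p under 0.05 and cameraPR adjusted p = 0.44.

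Males on RD born to dams on HCD showed lower miR-142a-5p and miR-33-5p as well. In the authors' deposited table, miR-142a-5p fell to 0.178 of RD-RD (log2 fold -2.49, implied standard error 0.33, adjusted p = 2.9e-11) and miR-33-5p to 0.207 (log2 fold -2.27, implied standard error 0.31, adjusted p = 8.3e-11). miR-101a-3p and miR-101b-3p, which repress the histone methyltransferase Ezh2, stood at 0.238 and 0.365 of RD-RD in the authors' deposited table, with adjusted p-values of 5.3e-07 and 4.1e-06. The largest rise with no low-count remark was that of miR-342-5p, from an intron of Evl on chromosome 12 (108658620 to 108658718), at 3.58-fold in the authors' deposited table (log2 fold 1.84, implied standard error 0.36, adjusted p = 2.2e-05). Also higher in the authors' deposited table were let-7b-5p at 2.44-fold, miR-92b-3p at 1.99-fold, miR-1198-5p at 2.04-fold, miR-664-3p at 2.46-fold and miR-574-3p at 2.6-fold. In all, 262 of 1426 miRNAs passed an adjusted p under 0.05, 91 higher and 171 lower, with 458 at an unadjusted p under 0.05. Without low-count miRNAs 193 of 765 passed, 94 higher and 99 lower, so the share of higher calls was 34.7% over all and 48.7% without remarks.

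In HCD-RD males 10 of 11 let-7 and miR-98 members rose, also 10 adjusted over the list alone, with cameraPR adjusted p = 1.4e-09 and a median fold of 1.8. Of the inflammation-related list 4 rose and 3 fell (8 and 3 adjusted over the list alone; cameraPR adjusted p = 0.025), a list call that ended at adjusted p = 0.13 with the preset correlation of 0.05. Here miR-132-3p, induced by neuronal activity, stood at 1.72-fold, miR-155-5p at 2.04-fold and miR-21a-5p at 0.538 of RD-RD in the authors' deposited table. In the Dlk1-Dio3 cluster 10 of 100 rose and 21 fell (12 and 22 adjusted over the list alone; cameraPR adjusted p = 0.74), with miR-136-3p at 0.392, miR-376a-3p at 0.329 and miR-433-3p at 2.82-fold in the authors' deposited table. Of the lipid and glucose list 4 fell and miR-370-3p rose (6 and 1 adjusted over the list alone; cameraPR adjusted p = 0.17), and miR-335-5p was among those that fell. All members of the sensory-cell miR-183 cluster listed among hypothalamic and neuroendocrine miRNAs fell (0 of 15 rose and 3 fell, the same adjusted over the list alone; cameraPR adjusted p = 0.44), with miR-96-5p at 0.204, miR-183-5p at 0.353 and miR-182-5p at 0.376 of RD-RD in the authors' deposited table. Single markers passed in both directions. Lower ones included both arms of miR-142a, miR-144-3p, miR-126a-3p, miR-219a-5p and miR-34b-5p, and higher ones miR-155-5p, miR-204-5p, miR-338-5p, miR-486a-5p and miR-145a-3p, the last 2 at 1.68- and 1.91-fold in the authors' deposited table. Of 18 neuron-enriched miRNAs 2 rose and 2 fell (3 and 3 adjusted over the list alone), of 9 choroid plexus and ependymal markers 3 and 2 (5 and 3), and of 8 microglial and leukocyte markers 1 and 2 (1 and 3). Of 6 erythrocyte markers 1 rose and 2 fell (2 and 2 adjusted over the list alone), of 5 oligodendrocyte markers 1 and 2 (the same), of 10 endothelial and mural markers 1 and 1 (1 and 4), and of 8 muscle and liver markers 0 and 1 (the same). No marker list passed cameraPR in HCD-RD males, with adjusted p-values between 0.44 and 0.86.

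**Figure D2:**
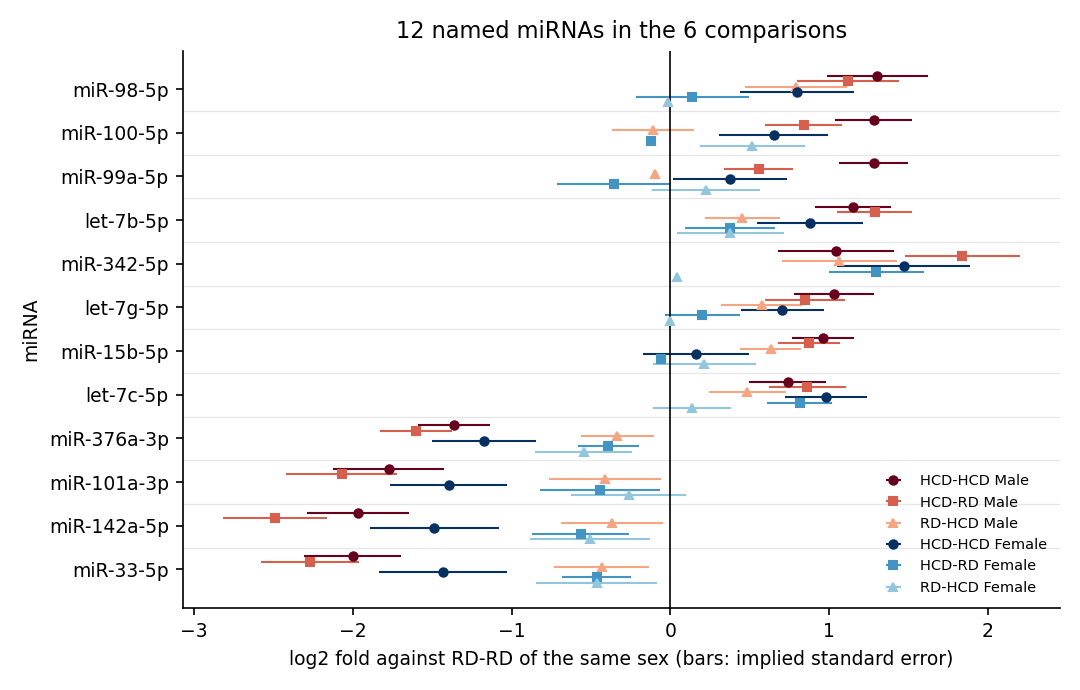
log2 fold against RD-RD of the same sex for 12 named miRNAs in the 6 comparisons, with bars for the standard error implied by the deposited fold and p (no bar where the fold was near 1 or had no p). miR-33-5p and miR-142a-5p lie farthest left in HCD-RD males, and the let-7 members lie right of 0 in males of dams on HCD.

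Males on HCD born to dams on RD showed few changes among miRNAs with no low-count remark. Both from the Dlk1-Dio3 cluster, miR-666-5p and miR-412-5p stood at 0.493 and 0.621 of RD-RD in the authors' deposited table (implied log2 standard errors 0.27 and 0.20, adjusted p-values 0.02 and 0.04). miR-3966 rose to 2.68-fold in the authors' deposited table (log2 fold 1.42, implied standard error 0.42, adjusted p = 0.044). Most of the others that passed had a low-count remark, led by miR-297b-5p at 0.174, miR-5123 at 0.193 and miR-1955-5p at 0.196 of RD-RD in the authors' deposited table. In all, 21 of 1426 miRNAs passed, 2 higher and 19 lower, 17 of them with a remark, and 178 had an unadjusted p under 0.05. Over the 860 miRNAs with no remark, Benjamini-Hochberg adjustment of the deposited DESeq2 p-values left 0, with 69 at an unadjusted p under 0.05. None of the 11 let-7 and miR-98 members passed, over all or adjusted over the list alone, yet the list scored above other miRNAs (median fold 1.29, cameraPR adjusted p = 1.4e-06, 3 members at an unadjusted p under 0.05). The Sfmbt2 cluster scored upward (cameraPR adjusted p = 0.024), with 0 higher and 1 lower of 38 and the same adjusted over the list alone, a list call that ended at adjusted p = 0.2 with the preset correlation of 0.05. In the Dlk1-Dio3 cluster 2 of 100 fell and 0 rose, also when adjusted over the list alone (cameraPR adjusted p = 0.84, and 0.047 without low-count miRNAs). Of 15 hypothalamic and neuroendocrine miRNAs 0 passed over all miRNAs and 2 were lower adjusted over the list alone. That list had cameraPR adjusted p = 0.25, and 0.02 without low-count miRNAs, a restriction chosen after the data were seen. miR-33-5p and miR-142a-5p did not pass here, at 0.741 and 0.775 of RD-RD in the authors' deposited table.

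Among males on HCD, those born to dams on HCD had higher miR-100-5p and miR-99a-5p and lower miR-33-5p and miR-142a-5p than those born to dams on RD. The authors' deposited table of this comparison lists 47 miRNAs at a fold of at least 2 and p up to 0.05, 10 higher and 37 lower, of which 28 have no low-count remark. It is a filtered list, so no adjustment was made, and 43 of the 47 had an unadjusted p under 0.01. In HCD-HCD, miR-100-5p stood at 2.59-fold and miR-99a-5p at 2.48-fold of the RD-HCD level in the authors' deposited table, with implied log2 standard errors of 0.21 and 0.25 and unadjusted p-values of 1.1e-10 and 2.1e-07. miR-33-5p and miR-142a-5p stood at 0.35 and 0.365 of the RD-HCD level in the authors' deposited table, with unadjusted p-values of 7.8e-07 and 4.6e-05. Also lower there were miR-301a-3p at 0.389, miR-29b-3p, a regulator of matrix genes, at 0.429, and miR-153-3p, a repressor of synaptic vesicle proteins, at 0.459 in the authors' deposited table. The level of miR-181b-5p was 2.03-fold that of RD-HCD in the authors' deposited table.

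The contrasts between male groups that follow, computed from the deposited folds, were chosen after the data were seen. The first difference, computed as the difference of the deposited log2 folds against RD-RD, called 35 of 715 miRNAs with no remark at an adjusted p under 0.05, 15 higher and 20 lower. Its values for the 47 listed miRNAs had the same sign in 47 and a Pearson correlation of 0.962 with the authors' values, across miRNAs, which are not independent replicates. Both sets of values come from the same libraries, and the 47 were listed for a fold of at least 2. So this agreement was largely fixed beforehand and checks only the computation. Averaged over both offspring diets, 215 of 715 miRNAs differed between males of dams on HCD and of dams on RD, 110 higher and 105 lower. That test took libraries as the unit, since dams and litters are not given. The mean log2 difference was -2.05 for miR-142a-5p (standard error 0.24, adjusted p = 2.3e-15), -1.92 for miR-33-5p (standard error 0.22) and 0.88 for miR-92b-3p (standard error 0.14). Of 11 let-7 and miR-98 members 10 rose in that average, and 10 rose in HCD-RD minus RD-RD, while in HCD-HCD minus RD-HCD all 11 lay above 0 (median fold 1.37) with 0 at an adjusted p under 0.05. For the offspring's diet, Benjamini-Hochberg adjustment of the normal tests from implied errors called 0 of 715, with 44 at an unadjusted p under 0.05 where 35.75 were expected by chance. The interaction of both diets likewise gave 0, with 53 at an unadjusted p under 0.05. HCD-RD and RD-RD males lie in different library sets, while at least 2 of the 3 RD-HCD male libraries share the set of HCD-HCD males.

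**Figure D3:**
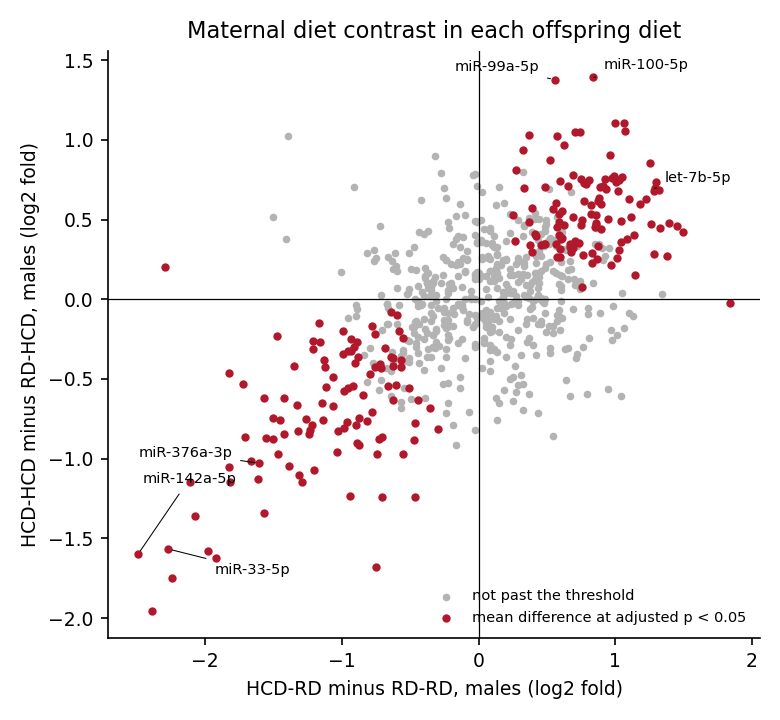
Each point is 1 of 715 miRNAs with no low-count remark in males, with HCD-RD minus RD-RD on the x axis and HCD-HCD minus RD-HCD on the y axis (both log2 fold). Red points pass an adjusted p under 0.05 for the mean of both differences, and the axes share no libraries but may share dams (Spearman 0.578).

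Differences by the dam's diet were next compared between the offspring diets on separate libraries. HCD-HCD minus RD-HCD and HCD-RD minus RD-RD share no libraries, and their Spearman correlation across 715 miRNAs, which are not independent replicates, was 0.578, with a covariance of 0.210. Dams and litters are not given, so groups with the same maternal diet may share dams. Both differences may therefore not be independent. Both called 8 of the same miRNAs higher (2.01 for independent lists) and 17 lower (2.80 for independent lists). For comparisons that share the RD-RD libraries, the Spearman correlation between HCD-HCD and HCD-RD males was 0.777, beside 0.404 in simulated unchanged groups, and the covariance was 0.385 beside 0.0621. These shared 55 higher and 131 lower miRNAs, against 5.11 and 23.4 for independent lists. Of the shared calls, 54 higher and 66 lower had no low-count remark (9.89 and 11.9 for independent lists). RD-HCD males correlated with HCD-HCD at 0.672 (simulated 0.409, covariance 0.209 beside 0.0627) and with HCD-RD at 0.688 (simulated 0.407, covariance 0.217 beside 0.0623). Of the 19 miRNAs lower in RD-HCD males, 18 were lower in HCD-HCD (2.60 for independent lists) and 18 in HCD-RD (2.28 for independent lists). Among miRNAs with no low-count remark, a restriction chosen after the data were seen, only 3 of these calls were left, of which 3 were lower in HCD-HCD (0.363 for independent lists) and 2 in HCD-RD (0.382 for independent lists). The controls could not be split without values per sample. The simulated values allow for the shared RD-RD libraries, but the counts for independent lists do not. So part of the excess in shared calls may come from those libraries. Library set is allowed for in neither. All HCD-HCD and HCD-RD male libraries and at least 2 of the 3 RD-HCD ones lie in another set than RD-RD, which may add to each excess.

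In females on HCD born to dams on HCD, 1 miRNA passed. In the authors' deposited table, miR-664-3p, from an intron of Rab3gap2 on chromosome 1 (185242975 to 185243043), rose to 2.66-fold (log2 fold 1.41, implied standard error 0.34, adjusted p = 0.041). Several miRNAs that fell in males had low values without passing over all miRNAs, with miR-142a-5p at 0.357, miR-33-5p at 0.37, miR-376a-3p at 0.442 and miR-101a-3p at 0.38 of RD-RD in the authors' deposited table. let-7c-5p stood at 1.97-fold and miR-342-5p at 2.77-fold in the authors' deposited table, at adjusted p-values of 0.058 and 0.07. In all, 84 of 1497 miRNAs had an unadjusted p under 0.05, where 74.85 were expected by chance. All 84 lay among the 648 miRNAs with no low-count remark, where 32.4 were expected. Adjusted over the 648 miRNAs with no low-count remark, 11 passed, 3 higher and 8 lower. Among the 11 were miR-664-3p, let-7c-5p and miR-342-5p, all higher, and miR-101a-3p, miR-142a-5p, miR-33-5p and miR-376a-3p, all lower, at adjusted p-values between 0.018 and 0.03.

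The let-7 and miR-98 family scored above other miRNAs in HCD-HCD females (cameraPR adjusted p = 2.2e-11), with a median fold of 1.57. None of its 11 members passed over all miRNAs and 4 did when adjusted over the list alone, all higher. The neuron-enriched, lipid and glucose, miR-29 and miR-17 to miR-92 lists scored below other miRNAs, with cameraPR adjusted p-values of 0.016, 0.016, 0.033 and 0.032. Those calls ended with the preset correlation of 0.05, at adjusted p = 0.1, 0.088, 0.088 and 0.13. No member of these lists passed over all miRNAs, with 4 neuron-enriched, 3 lipid and glucose, 1 miR-29 and 3 miR-17 to miR-92 members lower at an unadjusted p under 0.05. Adjusted over the list alone, 2, 1, 0 and 2 members were lower. Their lowest members included miR-138-5p at 0.518, a regulator of dendritic spines, and miR-19b-3p at 0.452 of RD-RD in the authors' deposited table.

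Females on RD born to dams on HCD had higher miR-151-5p and lower miR-380-5p and miR-7a-5p. In the authors' deposited table, miR-151-5p, from an intron of the focal adhesion kinase gene Ptk2 on chromosome 15 (73254815 to 73254882), rose to 2.79-fold (log2 fold 1.48, implied standard error 0.27, adjusted p = 9.3e-05). miR-380-5p of the Dlk1-Dio3 cluster fell to 0.472 in the authors' deposited table (log2 fold -1.08, implied standard error 0.21, adjusted p = 1.8e-04). The neuroendocrine miR-7a-5p, abundant in the hypothalamus, fell to 0.439 in the authors' deposited table (log2 fold -1.19, implied standard error 0.32, adjusted p = 0.023). Also higher in the authors' deposited table were miR-674-5p at 2.07-fold, miR-27b-5p at 2.46-fold, miR-24-3p at 1.7-fold, miR-342-5p at 2.46-fold and let-7c-5p at 1.76-fold. Lower ones were miR-298-5p at 0.361, miR-490-3p at 0.481, miR-135a-5p at 0.426 and miR-146b-5p, which limits NF-kappaB signalling, at 0.645 in the authors' deposited table. In all, 22 of 1298 miRNAs passed, 13 higher and 9 lower, with 149 at an unadjusted p under 0.05 where 64.9 were expected by chance, and 94 of these among 755 miRNAs with no low-count remark where 37.75 were expected.

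In HCD-RD females 1 of 11 let-7 and miR-98 members rose, also adjusted over the list alone, with a median fold of 1.19 and cameraPR adjusted p = 0.0047. With log2 fold as the statistic that call ended at adjusted p = 0.068. The hypothalamic and neuroendocrine list scored below other miRNAs (cameraPR adjusted p = 0.037), with miR-7a-5p lower over all miRNAs and 2 of 18 lower adjusted over the list alone, a call that ended at adjusted p = 0.17 with the preset correlation of 0.05. In the Dlk1-Dio3 cluster 1 of 98 rose (miR-154-3p) and 2 fell (miR-380-5p and miR-136-3p), the same adjusted over the list alone (cameraPR adjusted p = 0.051, 0.0051 without low-count miRNAs, and 0.41 with the preset correlation of 0.05). Of the inflammation-related list miR-24-3p rose and miR-146b-5p fell, the same adjusted over the list alone (cameraPR adjusted p = 0.51). Values for miR-33-5p and miR-142a-5p were 0.725 and 0.676 of RD-RD in the authors' deposited table and did not pass. No marker list passed cameraPR in HCD-RD females, with adjusted p-values between 0.43 and 0.74. The HCD-RD female libraries were normalised in a separate table with the same RD-RD libraries.

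Females on HCD born to dams on RD had no miRNA past the threshold. Adjustment of the deposited DESeq2 p-values by Benjamini-Hochberg called 0 of 1497, with a smallest adjusted p of 0.932, and 15 had an unadjusted p under 0.05 where 74.85 were expected by chance. All 15 lay among the 847 miRNAs with no low-count remark, where 42.35 were expected. The smallest deposited p-values belonged to miR-5627-3p at 0.348, miR-7004-5p at 0.382 and miR-1298-5p at 1.79-fold of RD-RD in the authors' deposited table. The choroid plexus marker miR-204-5p stood at 1.58-fold and the neuroendocrine miR-7b-5p at 0.613 in the authors' deposited table, without passing. Dlk1-Dio3 miRNAs scored below other miRNAs (median log2 fold -0.10, cameraPR adjusted p = 4.9e-06 and 0.034 with the preset correlation of 0.05), while 0 of 100 passed over all miRNAs or adjusted over the list alone. The list test rests on the spread across miRNAs and the preset correlation, not on the spread between libraries. Neighbours inside the Dlk1-Dio3 and Sfmbt2 clusters moved together here (pair correlation 0.180, another measure than the preset). So the p-values of this list may be too small. The hypothalamic and neuron-enriched lists scored below other miRNAs (cameraPR adjusted p = 0.0047 and 0.0068) and the choroid plexus list above (0.016), calls that ended at adjusted p = 0.057, 0.062 and 0.062 with the preset correlation of 0.05. No member of these 3 lists passed over all miRNAs or adjusted over the list alone. In simulated data for this comparison, 47% of miRNAs changed 2-fold and 92% of those changed 3-fold were recovered, against 0.5% of those changed 1.5-fold. The simulated noise followed the implied standard errors, with a median of 0.400. The deposited log2 folds of miRNAs with no low-count remark spread less, with a standard deviation of 0.227. So the simulation was noisier than these data, and the recovered shares do not settle which changes were detectable.

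Folds in males and females were compared for each diet pair across miRNAs, which are not independent replicates. For HCD-HCD the Spearman correlation between the sexes was 0.500 over 1342 miRNAs and 0.691 over the 628 with no low-count remark, and 224 of 274 miRNAs called in males had the same sign in females. miR-33-5p, miR-142a-5p and miR-376a-3p were below RD-RD and let-7 members above it in both sexes, though in females none of these passed over all miRNAs. Adjusted over miRNAs with no low-count remark, miR-33-5p, miR-142a-5p, miR-376a-3p and let-7c-5p passed in females as well. For HCD-RD the correlation was 0.413, and 193 of 253 miRNAs called in males had the same sign in females. For RD-HCD it was 0.0164, with the same sign for 10 of 20. In HCD-HCD and HCD-RD, the libraries of both sexes lie in another set than RD-RD, so the set may add to the agreement. In RD-HCD, the females lie in the set of RD-RD and most male libraries do not. Agreement from diet and agreement from set were not told apart here. The difference between the sexes, a test chosen after the data were seen and made from the implied errors with Benjamini-Hochberg adjustment of normal p-values, called 0 of 628 miRNAs for HCD-HCD, with 22 at an unadjusted p under 0.05. It called 18 of 695 for HCD-RD, 15 of them lower in males, with 119 at an unadjusted p under 0.05. It called 0 of 796 for RD-HCD, with 12 at an unadjusted p under 0.05. Males and females were normalised in separate tables, so only folds within a table entered these tests.

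**Figure D4:**
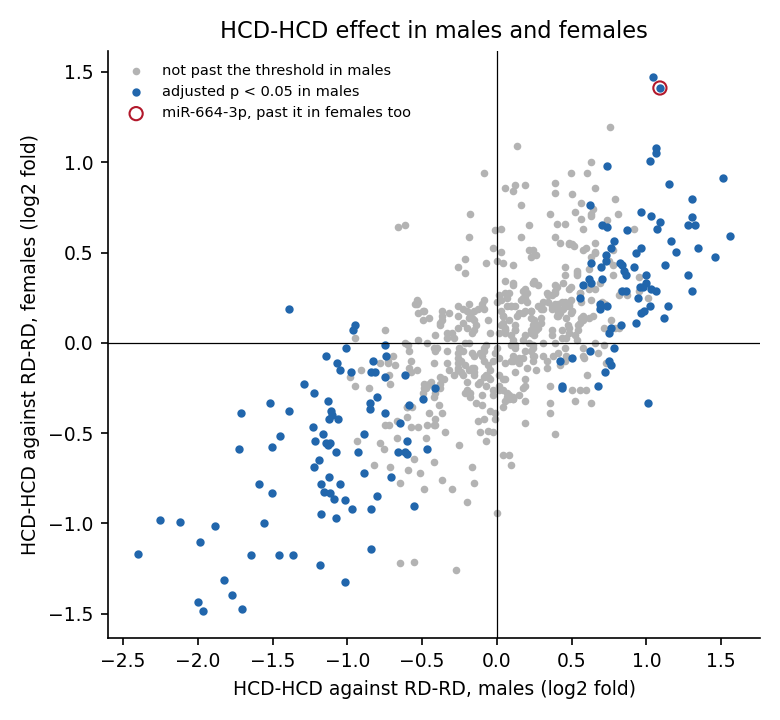
Each point is 1 of 628 miRNAs with no low-count remark in both sexes, with the HCD-HCD log2 fold against RD-RD in males (x axis) and females (y axis). Blue points pass an adjusted p under 0.05 in males, and the circle marks miR-664-3p, at 2.66-fold in females in the authors' deposited table (Spearman 0.691).

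Among females, Spearman correlations between the diet comparisons lay below those of simulated unchanged groups against the same controls. The correlation was 0.365 between HCD-HCD and HCD-RD (simulated 0.481), with a covariance of 0.0503 beside 0.0592. Without low-count miRNAs that covariance was 0.0874 beside 0.0642, and part of it may come from the shared RD-RD libraries, which could not be split. The correlation was 0.454 between HCD-HCD and RD-HCD (simulated 0.474, covariance 0.0306 beside 0.0542) and 0.230 between HCD-RD and RD-HCD (simulated 0.477, covariance 0.0156 beside 0.0585). Simulated values rest on the implied standard errors. In RD-HCD females these had a median of 0.400, above the standard deviation of 0.227 of the log2 folds with no low-count remark, so the simulated covariances may be too high. Adjusted over all miRNAs, HCD-HCD females had 1 call, and none was called in more than 1 of the 3 female comparisons, where independent lists of HCD-HCD and HCD-RD calls would share 0.0102 higher miRNAs. Adjusted over miRNAs with no low-count remark, a restriction chosen for overlaps after the data were seen, let-7c-5p and miR-342-5p were higher in both HCD-HCD (adjusted p = 0.025 and 0.03) and HCD-RD (0.0061 and 0.0018). The calls rest on Benjamini-Hochberg adjustment of the deposited DESeq2 p-values, with 84, 149 and 15 miRNAs at an unadjusted p under 0.05 in HCD-HCD, HCD-RD and RD-HCD females.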

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

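All the tests of explanations in this part, and the test of the difference between the sexes, were chosen after the results were seen.

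The effect of HCD-RD against RD-RD differed between males and females for 18 of 695 miRNAs with no low-count remark, by a normal test of the difference with Benjamini-Hochberg adjustment. Of these, 15 were lower and 3 higher in males than in females, and 10 had opposite signs. The 8 with the smallest p, named after their values were seen, had the following differences of log2 fold, male minus female. For miR-136-5p of the Dlk1-Dio3 cluster it was -1.91 (standard error 0.36, adjusted p = 0.00011), with folds of 0.34 in males and 1.28 in females in the authors' deposited tables. For miR-33-5p it was -1.80 (standard error 0.38, adjusted p = 0.00058). The miR-142 hairpins gave -1.38 for miR-142a-3p, -1.92 for miR-142a-5p and -1.68 for miR-142b. For miR-29b-3p it was -1.64, with folds of 0.521 in males and 1.62 in females in the authors' deposited tables. It was -1.21 for miR-376a-3p and -2.26 for miR-542-3p. The female HCD-RD libraries were normalised apart from the males, but 25 differed with the difference centred on its median, which argues against a common offset as the cause, and no other explanation was tested.

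The piRNA entries, which entered no comparison, had more small p-values than chance gives in 3 comparisons. At an unadjusted p under 0.05 there were 18 of 89 in HCD-HCD males and 17 of 89 in HCD-RD males (4.45 expected by chance), and 12 of 82 in HCD-RD females (4.1 expected). Among entries with no low-count remark these were 12 and 13 of 51 in males (2.55 expected) and 4 of 48 in HCD-RD females (2.4 expected), so in females most of the excess lay in low-count entries. After Benjamini-Hochberg adjustment of the deposited DESeq2 p-values among piRNA entries, 5, 5 and 0 passed. At an unadjusted p under 0.05 the other 3 comparisons had 5 of 89 in RD-HCD males (4.45 expected), 2 of 88 in HCD-HCD females and 6 of 88 in RD-HCD females (4.4 expected for each). After the same adjustment 0, 0 and 1 of these passed, and the 6 in RD-HCD females were all lower and all among the 51 with no low-count remark (2.55 expected).

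Males of dams on HCD differed from males of dams on RD in many miRNAs, among them lower miR-142a-5p and miR-33-5p and higher miR-92b-3p, miR-100-5p and let-7b-5p. GC content of the side of the hairpin that holds the mature arm explained at most 1.48% of the variance of the log2 folds, with rank correlations of -0.114 in HCD-HCD and 0.0887 in HCD-RD males, which argues against it as the cause. Library set as the whole cause was taken to act alike on both sexes, since HCD-RD and RD-RD libraries lie in the same sets in males and females. Yet 17 miRNAs that passed in HCD-RD males, among them miR-142a-5p and miR-33-5p, lay farther from 0 in males than in females at an adjusted p under 0.05, and 22 did with the difference centred on its median. This argues against a set that acts alike on both sexes as the whole cause for these miRNAs. A set that acts unequally on the sexes stays possible. The separate table of the HCD-RD females also stays possible as a source, since centring removes only a common offset. RD-HCD females, in the set of RD-RD, had 0 of 1497 miRNAs past Benjamini-Hochberg adjustment of the deposited DESeq2 p-values, with 15 at an unadjusted p under 0.05. Their folds had a Spearman correlation of 0.0164 with those of RD-HCD males, most of whose libraries lie in the other set. The set as part of the cause would also give these values, so that stays open. HCD-HCD males and females, which lie in the same sets, differed in 0 of 628 miRNAs by Benjamini-Hochberg adjustment of normal tests, with 22 at an unadjusted p under 0.05. For the 697 other miRNAs, RD-HCD males were set against the level that a set would give with 1 of their 3 libraries outside it. At an adjusted p under 0.05, 5 fell short of that level (miR-100-5p, miR-181a-5p, miR-181b-5p, miR-92a-3p and miR-92b-3p, named after their values were seen), and 48 did if no library lay outside. With 1 library outside, 49 had an unadjusted p under 0.05 where 34.85 were expected by chance, 39 short of the level and 10 beyond it. That level assumes that the deposited folds are ratios of arithmetic means, which was not checked. An alternative run first, with the set's share of 0.333 taken on the log2 scale, found 2 of 715 in HCD-HCD minus RD-HCD. So the set and the dam's diet cannot be told apart for these miRNAs, because the sets of the RD-HCD libraries leave a mixed level possible. The 5 do not settle it either, since the test takes the offspring's own diet to have no effect. The dam's diet, with an effect that depends on sex for some miRNAs, stays open as an untested explanation.

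Low-count miRNAs had median folds below 1 in all 3 male comparisons. One scaling offset for the whole table would move them as much as other miRNAs, yet in HCD-HCD males their median log2 fold lay at -0.42 relative to that of miRNAs with no remark, which argues against it. Over 364 miRNAs low in both groups of each comparison, the medians were -0.37 in HCD-HCD, -0.37 in HCD-RD and -0.32 in RD-HCD males, while HCD-HCD minus RD-HCD had a median of 0. A candidate explanation is something shared by the 3 comparisons, either the RD-RD libraries or how folds near the floor were made, and these were not separated. In females the medians of such miRNAs were 0.01, -0.14 and 0.07 in HCD-HCD, HCD-RD and RD-HCD.

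Members of a miRNA family moved together in HCD-HCD males. Across 204 pairs of relatives counted as unlinked, the log2 folds correlated at 0.52 (95th percentile of 1000 shuffles 0.134), and at 0.257 without let-7 (0.174). Each miRNA was placed at 1 hairpin, for let-7c-5p, let-7f-5p and miR-29b-3p at the copy numbered 1, and other copies were not considered. Pairs counted as unlinked may therefore include neighbours through another copy. So these values do not tell the mature sequence from joint transcription as the source. Each pair correlation here is the mean product of log2 folds standardised over all miRNAs with no low-count remark. A family that moves as a block, such as let-7, therefore raises it. Neighbouring hairpins within 10000 bp inside the Dlk1-Dio3 and Sfmbt2 clusters correlated at -0.033 over 966 pairs (shuffled 0.0619). This argues against a shared change in transcription as the source of the folds there in these males. Whether the hairpins are transcribed together was not tested. The evidence is weak, since both arms of one hairpin, which are always transcribed together, correlated at 0.179 over 228 pairs (shuffled 0.129). Elsewhere 173 neighbouring pairs correlated at 0.235 (shuffled 0.146). Reads shared between near-identical relatives stay open as a technical explanation, since the sequences behind each count were not used here. Neighbours inside the clusters did correlate in HCD-RD females, at 0.120 (shuffled 0.0602), and in RD-HCD females, at 0.180 (shuffled 0.0579). Relatives counted as unlinked correlated there at 0.238 and 0.155.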

How the results depend on the processing

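Settings chosen after the data were seen were the adjustment with piRNA entries, the derived difference of HCD-HCD and RD-HCD males, centring of the difference between the sexes (25 in place of 18 miRNAs in HCD-RD), and the restriction to miRNAs with no low-count remark for lists, overlaps and sexes. No called list changed direction under any setting run, and among correlations that of RD-HCD between the sexes, near 0, changed sign. No named miRNA that passed changed direction either, but other adjustments and filters keep the sign of the deposited fold. Only centring could have changed it. With only miRNAs that have no low-count remark, 177 passed in HCD-HCD males, 0 in RD-HCD males by Benjamini-Hochberg adjustment of the deposited DESeq2 p-values (69 at an unadjusted p under 0.05), 11 in HCD-HCD females and 28 in the list of HCD-HCD against RD-HCD males. Fewer miRNAs were tested there, and 10 named miRNAs passed that had not passed before. With a fold of at least 2, 168 passed in HCD-RD males and 14 in HCD-RD females, which follows from the added condition. Benjamini-Yekutieli adjustment left 122, 131 and 6 in HCD-HCD, HCD-RD and RD-HCD males, and 0 and 7 in HCD-HCD and HCD-RD females (84 and 149 at an unadjusted p under 0.05). Holm adjustment left 55, 69 and 7 in males and 7 in HCD-RD females. Both are stricter by construction. An unadjusted p under 0.01 was met by 278, 268 and 51 miRNAs in males and 37, 73 and 4 in females, in the order HCD-HCD, HCD-RD and RD-HCD. The 1.5-fold minimum and the piRNA entries moved no count by over 1.5 times. Centring on the median leaves p-values untouched and changed no count of higher or lower calls, and RD-HCD females stayed at 0 with 15 at an unadjusted p under 0.05. Over the settings without low-count miRNAs, Benjamini-Yekutieli and Holm, 281 values for named miRNAs kept their side of the threshold, 38 lost it and 10 gained it.

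Of 17 lists called in 96 tests, 7 were called with a preset correlation of 0.05, and 10, 12 and 8 of the 17 held with log2 fold, ranks and no low-count miRNAs. Other lists gained a cameraPR call. Without low-count miRNAs these were Dlk1-Dio3 in RD-HCD males (adjusted p = 0.047) and HCD-RD females (0.0051), the hypothalamic list in RD-HCD males (0.02), and muscle and liver in RD-HCD females (0.024). The last also gained with log2 fold (0.037), as did Sfmbt2 in HCD-HCD males (0.033, and 0.036 with ranks). The 5 called in every setting were let-7 in HCD-HCD, HCD-RD and RD-HCD males and HCD-HCD females, and the Dlk1-Dio3 cluster in RD-HCD females. No setting used a preset correlation above 0.05, and all rest on the spread across miRNAs. The correlation of HCD-HCD and HCD-RD males was 0.807 by Pearson and 0.839 without low-count miRNAs, that of HCD-HCD and HCD-RD females 0.443 without them, and that of HCD-HCD and RD-HCD females 0.515 by Pearson. Between the sexes it was 0.691 for HCD-HCD and 0.180 for RD-HCD without low-count miRNAs, and 0.472 for HCD-RD and -0.0405 for RD-HCD over miRNAs at an unadjusted p under 0.05 in one sex. The cause was not tested for lists and correlations.

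No paired analysis was possible because the tables give 1 fold and 1 p per comparison, with no value per library. For the same reason DESeq2 against edgeR, other scalings, count filters, a fit of only the compared groups, a replicate block, leaving out single libraries, an estimated correlation, other splits of the samples and a limit at the median level were not run. For the list of HCD-HCD against RD-HCD males, Benjamini-Yekutieli, Holm and fold minimums had no use, since it was already limited by fold and p. Depth was unknown, and changes of 1.5-fold were recovered for 0.5% to 19.5% of simulated miRNAs.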

Other observations

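The contrasts in this part were chosen after the data were seen.

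Between males of dams on HCD, the offspring's own diet gave no call: HCD-HCD minus HCD-RD had 0 of 715 miRNAs at an adjusted p under 0.05 by Benjamini-Hochberg adjustment of normal tests, with 52 at an unadjusted p under 0.05 where 35.75 were expected by chance. The smallest p-values belonged to miR-582-3p, with a log2 difference of 0.56 (standard error 0.15), and miR-544-5p of the Dlk1-Dio3 cluster, with 0.84 (standard error 0.23), both at adjusted p = 0.080. Averaged over both maternal diets, miR-350-3p had the smallest p for the offspring's diet, with a log2 difference of 0.71 (standard error 0.20, adjusted p = 0.150). For the interaction of both diets, miR-342-5p lay at -1.86 (standard error 0.53, adjusted p = 0.152) and miR-96-5p at 2.50 (standard error 0.75, adjusted p = 0.152). Across 715 miRNAs, which are not independent replicates, the offspring diet differences under each maternal diet, which share no libraries, had a Spearman correlation of -0.0934. HCD-HCD and HCD-RD males lie in one library set, while RD-RD males lie in another set than most RD-HCD male libraries. So the set may enter RD-HCD minus RD-RD, and with it the interaction and the offspring diet average.

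Males that differed in both diets, HCD-RD minus RD-HCD, had 58 of 715 miRNAs at an adjusted p under 0.05, 20 higher and 38 lower. The miR-92 relatives miR-92b-3p and miR-92a-3p were higher in HCD-RD by 1.28 (standard error 0.20, adjusted p = 7.8e-08) and 1.17 (standard error 0.24) on the log2 scale. miR-142a-5p differed by -2.12 (standard error 0.34) and miR-136-5p by -1.21 (standard error 0.24). Library set differs between these groups for at most 1 RD-HCD library.

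Dlk1-Dio3 miRNAs with no low-count remark spread about as much as others in HCD-HCD males, with a standard deviation of log2 folds of 0.669 beside 0.632 for all other miRNAs, a difference that was not tested.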
